A study of Homo sapiens with 16 samples.

How the data were processed

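The values used were the deposited gene counts, raw counts of reads per gene symbol for 28374 genes and 16 samples, all of which were read. Per the labels' protocols, total RNA was depleted of ribosomal RNA and made into strand-specific libraries, and 3 sequencing platforms were named without being tied to samples. The submitters' processing notes name HOMER and the builds hg19 and GRCh37; the aligner and gene annotation version are not given in the sources used here. Depth is given as the total count of each library.

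Control replicates 3 and 4 were equal at 100% of the 19340 genes with a count in either, while other pairs were equal at 0.418% to 2.60%, so this pair was used once. Group and replicate came from the labels. No pairing of replicates was used, because the labels give only a running number. X-inactivation and Y-linked genes were kept in the tests and no level of them was listed.

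Tests were run in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with its default smallest count of 10, which left 18575, and libraries were scaled by the trimmed mean of M values (TMM). All 15 libraries were fitted in 1 model with a term per group by edgeR's quasi-likelihood test, and p-values were adjusted by Benjamini-Hochberg over all tested genes at 0.05 per comparison. The comparisons were EGF, TPA and H89 against control, each mitogen with H89 against the mitogen and against H89, both interactions and TPA against EGF. Log2 fold changes are edgeR's, with SE from the test. Levels in CPM were TMM-scaled, except the median levels of lists and the levels of cell type markers, which were divided by the total count. Correlations and components used log2 CPM with a prior count of 2.

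The named genes were, per comparison, up to 8 largest rises and 8 largest falls among called genes with non-overlapping groups and a mean of at least 1 CPM. For interactions the groups were allowed to overlap. Also named were 15 preset genes, up to 4 examples per list in order of adjusted p, called or not, and the 5 genes of lowest p where none was called. The groups, main test, comparisons, preset genes and most alternatives were set before the data were examined. A term for any technical split was among them, but the libraries that form each batch were read from the counts. The GC correction, the copies of the control and the set without the 3 libraries that stand apart were chosen after seeing the data.

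Gene lists written from general knowledge were immediate-early transcription factors, feedback regulators of ERK and growth factor signalling, early secreted cytokines and growth factors, matrix proteases and prostaglandin and hyaluronan enzymes, SRF and MRTF targets, cAMP and CREB targets, NF-kappaB targets, S phase and mitosis genes, FOXO and growth-arrest genes, cholesterol and fatty acid synthesis, the unfolded protein and integrated stress response, p53 targets, fibroblast matrix and identity, genes studied earlier for MSK and histone H3 phosphorylation, histone genes, markers of keratinocytes, endothelial cells, melanocytes and leukocytes, and small structured RNAs. These 20 lists gave 200 tests by camera in limma 3.58.1 with a preset correlation of 0.01, adjusted together, and repeated with an estimated correlation. Mitochondrial transcripts were not analysed here.

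Alternatives were DESeq2 1.42.0, size factors in place of TMM, limma quality weights, no filter, at least 10 counts in 50% of the libraries, only the compared groups in the model, both control copies, a term for the technical batch, a block for sets of sample names, leaving out each library, leaving out the 3 libraries that stand apart, an added log2 fold threshold of 1, GC correction in 25 bins and fry for lists. GC content was known for 17426 of the tested genes. Genes induced in a limma fit of log2 CPM were compared with shuffled residuals, and the agreement of EGF and TPA with simulations of unchanged groups.

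The scripts were tested on simulated data with planted changes. At a planted change of 4-fold the main fit recovered 44.0% of changed genes for EGF against control and 17.2% for TPA+H89 against TPA, with false shares of 2.26% and 2.83% of calls, while for EGF+H89 against EGF the false share was 5.23%, above the 5% aimed at. With the batch term recovery was 97.0% and 79.1%, but false calls were 10.6% and 8.86%. For TPA+H89 against TPA the main fit recovered 0% of genes changed 2-fold. False shares were taken over planted changes of 2-, 4- and 8-fold together. Counts for the main fit were drawn with no batch, unlike these libraries, so its shares of recovered and false calls may not hold for them. A fold against a group with no count was left out, as was an analysis of coordinates.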

Results

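Messenger and other long RNAs were measured in CCD-1070Sk cells, a line of normal human skin fibroblasts, after serum starvation. The cells were left untreated, given epidermal growth factor (EGF, 30 ng/ml) for 1 h, or given the phorbol ester TPA (100 nM), an activator of protein kinase C, for 1 h. Each condition was also measured after 30 min with 10 µM H89, an inhibitor that acts on the kinases MSK1 and MSK2 and on protein kinase A. H89 alone is recorded as 30 min of pretreatment at 0 h, while in EGF+H89 and TPA+H89 1 h with the mitogen followed it. The time in H89 may therefore differ between these groups, and comparisons across them may mix it with the treatment. The labels name 16 samples: 4 control, 3 EGF, 2 TPA, 3 H89, 2 EGF+H89 and 2 TPA+H89. Control replicates 3 and 4 held identical counts at every gene and were counted as 1 sample, which left 15 libraries and 3 controls. The shared counts were assigned to control 3. By its running number control 4 belongs with TPA 2, H89 3 and TPA+H89 2, which were thus left without a control of their own set of sample names. In TPA against control, TPA 2 therefore cannot be separated from that set. TPA 1 shares its set of sample names with control 3, but not the technical batch described below. As no control shares both set and batch with either TPA library, TPA against control may mix the treatment with these. Nothing in the labels states that replicates came from separate cultures, so the p-values measure only the spread between these samples, which may be technical.

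The total count was 43565645, 20113265 and 33648925 in control replicates 1 to 3, and 41514691, 23422453 and 57270922 in EGF replicates 1 to 3. It was 33522696 and 130075914 in the TPA libraries and 28160371, 54594906 and 68230979 in the H89 libraries. The EGF+H89 libraries held 24047897 and 39091712 counts. TPA+H89 replicates 1 and 2 held 7527026 and 70470733, and RMRP, a structural RNA, took 13.4% of the counts of replicate 1.

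The libraries fell into 3 technical batches that crossed the groups. Control 1 and EGF 1 had more genes at a count of 1 (1185 and 1121) than at a count of 2 (785 and 701), while the reverse held in each other library. Control 2, EGF 2 and replicate 1 of TPA, H89, EGF+H89 and TPA+H89 gave 11.7% to 30.4% of their counts to the rRNA genes RNR1 and RNR2. Within this batch TPA 1 and TPA+H89 1 gave 11.7% and 12.0%, and the others 24.8% to 30.4%. In control 1 and EGF 1 that share was 4.48% and 0.0183%. The other 7 libraries had 0 counts at both. After the group means were removed, component 1 held 49.7% and component 2 held 21.6% of the remaining variance, and these followed the batches. Control 1, EGF 1 and TPA 2 had the lowest median correlations with the other libraries, at 0.885, 0.865 and 0.936. The number of genes called in each comparison is therefore given also with the batch as a term.

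**Figure D1:**
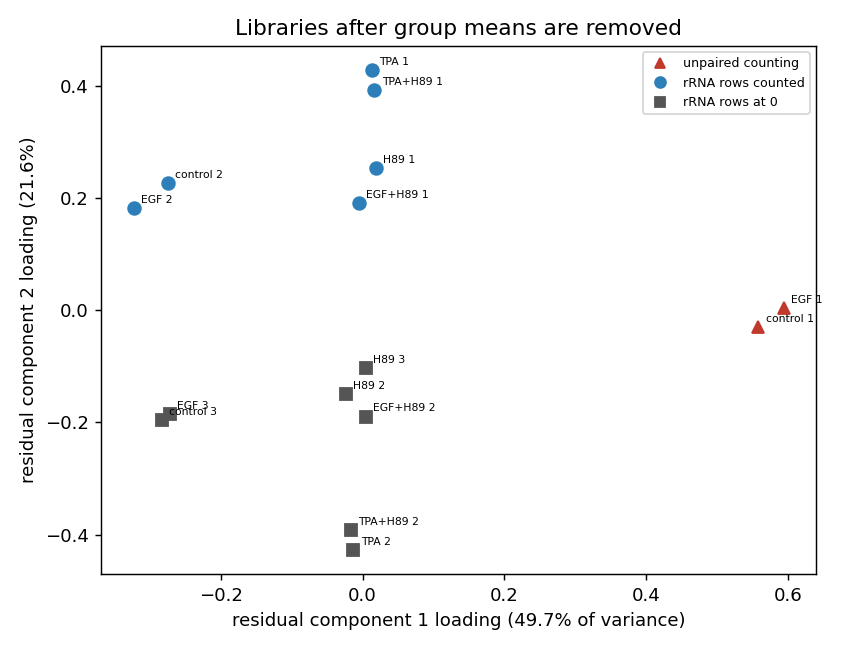
Loadings of the 15 libraries on components 1 and 2 of log2 CPM after group means were removed, with marks for the technical batches. Control 1 and EGF 1 lie apart on component 1 (49.7% of the variance), and the other libraries lie on opposite sides of component 2 (21.6%) according to whether the rRNA genes had counts.

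The comparison of EGF with control asked which genes responded to the growth factor within 1 h. Expression of EGR2, a zinc-finger transcription factor, rose from 7.72 ± 2.92 to 134 ± 81.6 CPM (mean ± SD, n = 3 and 3), a log2 fold change of 4.11 ± 0.52 (SE; adjusted p = 0.0207). The stress-responsive transcription factor ATF3 rose by 3.27 ± 0.45, and the nuclear factor CSRNP1 by 2.81 ± 0.37. DUSP5, a phosphatase of nuclear ERK, rose by 2.62 ± 0.30, and ERRFI1, an inhibitor of the EGF receptor, by 1.77 ± 0.23. These 5 genes were called higher and 0 lower among 18575 tested by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, with 303 genes at an unadjusted p under 0.05. That is below the 5% of tested genes that would be so without any change. The same held in the main fit for H89 against control, EGF+H89 against EGF, each mitogen with H89 against H89 and both interactions. Few or 0 calls in these are thus weak evidence of no change. Within the 3 batches the log2 difference of EGR2 was 2.10, 5.13 and 4.52, that of DUSP5 was 2.72, 2.89 and 2.31, and that of CSRNP1 was 2.66, 2.82 and 3.01.

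With the batch as a term, 41 genes were higher and 0 lower. In that fit NR4A1, an orphan nuclear receptor, rose by 3.60 ± 0.47 (adjusted p = 0.00179), the phosphatase DUSP1 by 2.95 ± 0.37 and the prostaglandin synthase PTGS2 by 2.87 ± 0.34. EGR3, IER3, KLF10, the cytokine LIF, the matrix protein CYR61 and MYC also rose in it, by 3.22, 2.23, 2.20, 2.24, 2.13 and 1.19. FOS stood at 2.67 ± 0.62 with the batch term (adjusted p = 0.131) and 1.64 ± 0.87 without it. FOSB was at −0.59 ± 1.07 without the term and 1.11 ± 0.77 with it, and passed neither test. Both were high in control 1, with FOS at 138 CPM against 5.10 and 15.7 in the other controls and FOSB at 28.8 against 0.0600 and 1.99. Without control 1 the FOSB value was 2.63.

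Of 24 immediate-early transcription factors, 2 rose (EGR2 and ATF3) and 22 did not pass the test over all genes. The number was 18 higher and 0 lower when adjusted over the list alone, and 10 higher with the batch term, among them BHLHE40, KLF6, MAFF and NR4A3. Their median log2 fold change was 1.72, and the list was higher than the other genes by camera at an adjusted p of 4.5e-78, with adjusted p = 0.000515 with an estimated correlation. The within-batch medians were 1.40, 2.37 and 1.83. Of 18 feedback regulators of ERK and growth factor signalling, DUSP5 and ERRFI1 rose, 9 rose when adjusted over the list alone and 5 with the batch term, and the median was 0.76 (adjusted p = 3.4e-27, and adjusted p = 0.0112 with an estimated correlation). That call was lost with the batch term and an estimated correlation (adjusted p = 0.147). Of 12 genes studied earlier for MSK and histone H3 phosphorylation, 11 of which are also in other lists, only ATF3 rose over all genes tested and 10 rose when adjusted over the list alone, with a median of 2.24 (adjusted p = 0.000515 with an estimated correlation). The 15 cAMP and CREB targets had 0 members called over all genes by edgeR and 2 when adjusted over the list alone; their median was 0.15 and their mean 0.57 (adjusted p = 2.8e-05, and adjusted p = 0.0168 with an estimated correlation, but adjusted p = 0.135 with the batch term and an estimated correlation).

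The 21 early secreted cytokines and growth factors had a median of 0.41 (adjusted p = 4.5e-09, but adjusted p = 0.113 with an estimated correlation), with 0 members called over all genes, 3 adjusted over the list alone and 3 with the batch term (HBEGF, IL11 and LIF). Within the 3 batches that median was 0.72, 1.38 and −0.05, the last with 12 of 21 members lower. The 20 fibroblast matrix and identity genes had a median of −0.19 (adjusted p = 0.0042, and adjusted p = 0.263 with an estimated correlation), and the 19 FOXO and growth-arrest genes one of −0.19 (adjusted p = 0.0106, and adjusted p = 0.356 with an estimated correlation). Neither had a member called over all genes or adjusted over the list alone. The p53 targets, at a median of 0.20, also lost their call (adjusted p = 0.303 with an estimated correlation). The NF-kappaB targets, at a median of 0.31, had an adjusted p of 0.0117, but adjusted p = 0.623 with an estimated correlation, and reversed without control 1 or EGF 2 (adjusted p = 0.755 and 0.779). DESeq2 called 61 genes higher and 1 lower in this comparison, and edgeR with only the control and EGF libraries in the fit called 0 of 15858 genes. Leaving out control 2 or EGF 2 left 0 calls, leaving out control 3 left 1, and leaving out EGF 1 gave 10; without control 1, EGF 1 and TPA 2 there were 23.

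The comparison of TPA with control asked the same of the phorbol ester. ARC, an immediate-early gene known from neurons, had a log2 fold change of 6.76 ± 1.19 (adjusted p = 0.0308), from 0.503 ± 0.365 to 57.9 ± 66.1 CPM (n = 3 and 2). The phosphatase DUSP2 rose by 6.57 ± 0.82, EGR3 by 6.36 ± 1.04, the transcriptional repressor HES1 by 5.99 ± 1.08 and NR4A1 by 5.73 ± 0.78. JUNB, EGR2 and IER3 rose by 5.66 ± 0.87, 5.49 ± 0.57 and 5.35 ± 0.84. EGFL6, a secreted protein with EGF-like repeats, fell by 5.12 ± 0.82 on the log2 scale, from 1.96 ± 0.579 CPM to 0.0558 ± 0.00875 CPM, which was 2 and 6 counts in the TPA libraries. MGP, an inhibitor of matrix calcification, fell by 2.24 ± 0.44, and BRF2, a subunit of an RNA polymerase III initiation factor, by 1.51 ± 0.26. In all, 72 genes rose and 5 fell, with 2453 at an unadjusted p under 0.05.

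With the batch as a term, 176 genes were higher and 57 lower. FOS, at 4.14 ± 1.00 without the term (adjusted p = 0.137), then rose by 5.92 ± 0.76 (adjusted p = 0.000603), and FOSB, at 3.46 ± 1.23, rose by 5.85 ± 0.91. The control 1 and EGF 1 batch holds no TPA library, and in the other batches the log2 differences were 6.27 and 5.32 for EGR2, 6.60 and 6.18 for NR4A1, 4.02 and 5.90 for JUNB and −3.70 and −4.53 for EGFL6. In each of these batches the TPA library and the control came from different sets of sample names.

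Of the 24 immediate-early transcription factors, 12 rose with TPA and 0 fell, among them NR4A3 (4.92 ± 0.48), ATF3 (4.60 ± 0.49), EGR1 (4.60 ± 0.76) and MAFF (3.75 ± 0.42). With adjustment over the list alone 22 rose, and with the batch term 20. The median was 3.51, and all 24 members had a positive value (adjusted p = 5.3e-64, and adjusted p = 0.00101 with an estimated correlation). Within the batches it was 3.09 and 4.07. Of the ERK and growth factor feedback regulators 6 of 18 rose, 9 when adjusted over the list alone and 8 with the batch term, among them DUSP1 by 4.80 ± 0.50, DUSP5 by 3.72 ± 0.33 and SPRY2, an inhibitor of receptor tyrosine kinase signalling, by 2.55 ± 0.27 (list adjusted p = 0.0255 with an estimated correlation, but 0.277 with the batch term and an estimated correlation). Of the genes studied earlier for MSK, 7 of 12 rose, and 12 when adjusted over the list alone, including PTGS2 by 4.67 ± 0.68 (list adjusted p = 0.000798 with an estimated correlation). Of the cAMP and CREB targets, NR4A1 and NR4A3 rose; adjusted over the list alone 10 were higher and 1 lower, and the median was 1.40 (adjusted p = 0.00337 with an estimated correlation, but adjusted p = 0.0640 with the batch term and an estimated correlation).

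Among 21 early secreted cytokines and growth factors 4 rose: the cytokines IL11 (4.04 ± 0.60), GDF15 (4.02 ± 0.75) and LIF (3.71 ± 0.55), and HBEGF (3.22 ± 0.61), a ligand of the EGF receptor. The list's median was 1.27, and 5 rose when adjusted over the list alone and 5 with the batch term (adjusted p = 2.5e-09, but adjusted p = 0.102 with an estimated correlation). Within batches its median was 1.80 and 0.43. INSIG1, which retains the regulators of sterol synthesis in the endoplasmic reticulum, rose by 3.34 ± 0.53. It was the only one of 18 cholesterol and fatty acid synthesis genes to rise over all genes tested, while 10 rose when adjusted over the list alone, and all 18 had a positive value (median 1.32; adjusted p = 1.1e-10, but adjusted p = 0.248 with an estimated correlation). Within batches the median was 1.63 with 18 of 18 higher and 0.34 with 14 of 18 higher. The median level of this list was 239 CPM in H89 3, which got no TPA, against 210.5 and 93.9 with TPA. It was 57.0 to 84.0 in the controls. For the SRF and MRTF targets that level was 818 in H89 3, 743 and 731 with TPA and 300 to 387 in the controls. H89 1 and 2 stood at 70.4 and 82.4 CPM for the cholesterol list and at 314.5 and 348 for the SRF and MRTF list. TPA+H89 1 and 2 stood at 152 and 156, and at 592 and 517. With H89 alone the high levels were thus those of H89 3, which is of the set of sample names of TPA 2 and TPA+H89 2. Of the SRF and MRTF cytoskeletal targets CYR61 rose by 2.47 ± 0.34, and 6 of 18 rose when adjusted over the list alone (median 0.84, and 0.68 and 1.32 within batches; adjusted p = 7.6e-08, but adjusted p = 0.192 with an estimated correlation). The NF-kappaB targets had a median of 1.08, which was 0.57 with the batch term and 0.31 and 0.56 within batches, with 0 members called over all genes and 3 adjusted over the list alone (adjusted p = 1.9e-05, but adjusted p = 0.352 with an estimated correlation).

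The matrix proteases and prostaglandin and hyaluronan enzymes had a median of 0.58, with PTGS2 called, 4 higher and 2 lower when adjusted over the list alone (adjusted p = 0.0482, but adjusted p = 0.352 with an estimated correlation). The p53 targets had a median of 0.39 with GDF15 called, 6 when adjusted over the list alone (adjusted p = 1.9e-05, but adjusted p = 0.192 with an estimated correlation). The 15 histone genes had a median of 0.74 and the 16 genes of the unfolded protein and integrated stress response one of 0.54; 0 of either list was called over all genes, and 2 and 0 when adjusted over the list alone (adjusted p = 0.00661 and 0.0147, but adjusted p = 0.311 and 0.589 with an estimated correlation). The S phase and mitosis genes, at a median of 0.29, the FOXO and growth-arrest genes, at 0.06, and the fibroblast matrix and identity genes, at −0.41, did not pass as lists (adjusted p = 0.184, 0.302 and 0.0737). The fibroblast median was −0.07 with the batch term and 0.06 and −0.44 within batches. The matrix proteases, p53 targets and histone genes were not called with the batch term at the preset correlation (adjusted p = 0.0864, 0.0506 and 0.116).

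**Figure D2:**
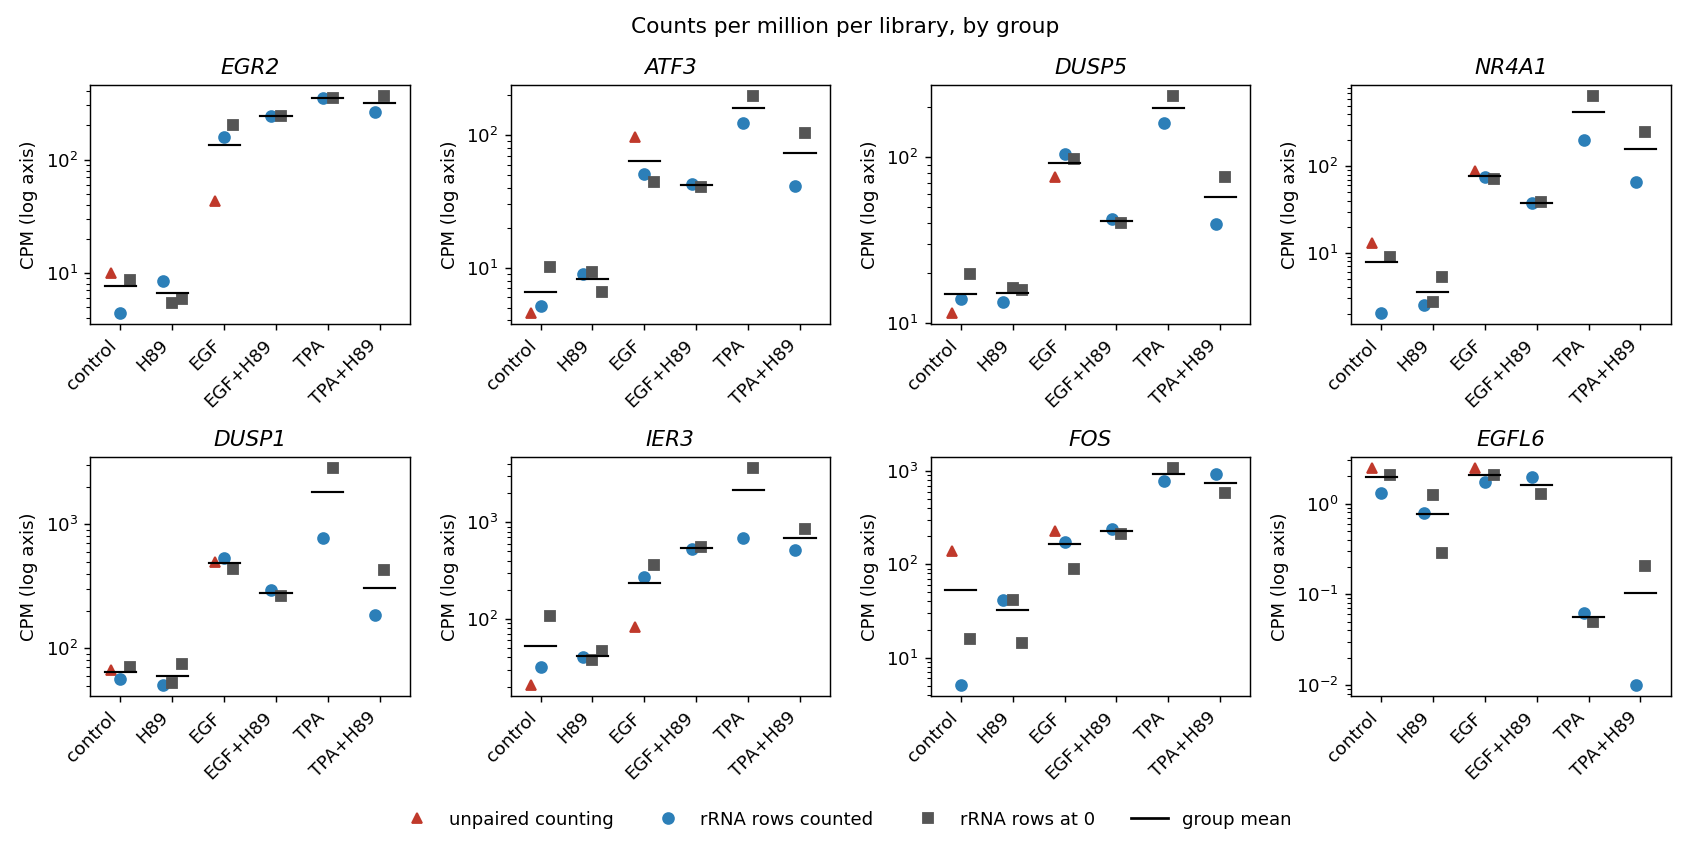
Level in CPM of each library on a log axis for 8 genes in the 6 groups, with a mark for each technical batch and a line at each group mean; the value of 0 for EGFL6 in TPA+H89 replicate 1 is drawn at the bottom of its axis. EGR2 stood at 4.44 to 10.0 in the controls, 43.0 to 201 with EGF and 347 to 350 with TPA, and EGFL6 was lowest in the TPA and TPA+H89 libraries.

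The number of genes called with TPA depended on single libraries. It was 13 without TPA 2, 13 without control 2, 17 without control 3, 31 without control 1 and 1187 without TPA 1, where TPA 2 alone stood for the group and was assumed to vary like the other groups. DESeq2 called 324 genes higher and 200 lower, and edgeR with only the control and TPA libraries in the fit called 0 of 15923 genes.

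In the comparison of H89 with control, which asked what the inhibitor did without a mitogen, 0 genes passed by edgeR, with 608 at an unadjusted p under 0.05; the batch term also gave 0, and DESeq2 called 0 higher and 3 lower. The lowest p-values belonged to KLB, the co-receptor for hormone-like fibroblast growth factors (−3.34 ± 0.71; 0.605 ± 0.435 CPM in controls and 0.0608 ± 0.0158 with H89, n = 3 and 3), to the disaccharidase TREH (−2.82 ± 0.67), to SPACA6P-AS (−2.99 ± 0.77), to HRAT92 (−2.60 ± 0.67) and to ANO7 (−2.00 ± 0.53). NR4A1 was at −1.18 ± 0.63 and EGR1 at 1.21 ± 0.64. The immediate-early list had a median of −0.13 (adjusted p = 0.722).

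The cholesterol and fatty acid synthesis list was higher with H89, with a median of 0.98 and all 18 members positive (adjusted p = 5.9e-12, but adjusted p = 0.239 with an estimated correlation), though 0 members passed over all genes or adjusted over the list alone. Its within-batch medians were 0.12 and 0.89, and INSIG1 stood at 239 CPM in H89 3 against 57.2 and 59.4 in the other H89 libraries. The S phase and mitosis genes had a median of 0.56, which was 0.25 with the batch term and 0.15 and 0.32 within batches (adjusted p = 5.7e-07, but adjusted p = 0.113 with an estimated correlation), and the SRF and MRTF targets one of 0.34 (adjusted p = 0.000473, but adjusted p = 0.353 with an estimated correlation). The SRF and MRTF medians within batches were −0.09 with 16 of 18 lower and 0.78 with 17 of 18 higher, and the median level of the list was 818 CPM in H89 3 against 314 and 348 in H89 1 and 2. The NF-kappaB targets, at 0.18, and the histone genes, at 0.18, also lost their calls (adjusted p = 0.604 and 0.414 with an estimated correlation). The NF-kappaB median was −0.09 with the batch term, and with that term neither list was called at the preset correlation (adjusted p = 0.725 and 0.187). Within batches the medians were 0.35 and −0.35 for the NF-kappaB targets and −0.13 and 0.19 for the histone genes.

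Comparing EGF+H89 with EGF asked what the inhibitor did in cells given EGF. By edgeR 0 genes passed, with 310 at an unadjusted p under 0.05, 0 with the batch term and 1 lower by DESeq2. With limma quality weights 1 was higher and 20 were lower. PCF11, a factor of RNA cleavage and polyadenylation, had the lowest p, at −1.23 ± 0.23 (62.5 ± 4.19 CPM with EGF and 26.7 ± 2.67 with EGF+H89, n = 3 and 2; adjusted p = 1.00). Its log2 differences within batches were −1.23 and −1.30. CDHR5, ZNF93 and C9orf131 stood at −3.75 ± 0.72, −1.90 ± 0.42 and −2.67 ± 0.66, and MGC12916 at 1.79 ± 0.45. NR4A1 was at −1.03 ± 0.71 and DUSP1 at −0.81 ± 0.48.

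The immediate-early list had a median of 0.10 in EGF+H89 against EGF and a mean of −0.02 (adjusted p = 0.489), with 0 members called over all genes or adjusted over the list alone. Within batches its median was 0.00448 and 0.08. At the preset correlation and without the batch term, the lists called higher were the NF-kappaB targets (median 0.47; adjusted p = 4.8e-07, but adjusted p = 0.303 with an estimated correlation), the histone genes (0.31; adjusted p = 0.271 with an estimated correlation), the secreted factors (0.31; adjusted p = 0.432 with an estimated correlation), the FOXO and growth-arrest genes (0.20; adjusted p = 0.352 with an estimated correlation) and the p53 targets (0.21; adjusted p = 0.483 with an estimated correlation). None of their members passed over all genes or adjusted over the list alone. The secreted factors, p53 targets and FOXO genes were no longer called with the batch term at the preset correlation (adjusted p = 0.706, 0.684 and 0.107), and the NF-kappaB median was 0.25. Within batches the median was 0.06 and 0.23 for the NF-kappaB targets and 0.17 and −0.03 for the secreted factors.

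In TPA+H89 against TPA, the same question with the phorbol ester, 0 genes passed by edgeR, with 1300 at an unadjusted p under 0.05; with the batch term the numbers were 0 and 2484. DESeq2 called 2 higher and 7 lower. Among the 5 genes of lowest p, DUSP1 stood at −2.56 ± 0.54 (1805 ± 1462 CPM with TPA and 306 ± 170 with TPA+H89, n = 2 and 2; adjusted p = 0.713), DUSP5 at −1.78 ± 0.35 and the antiproliferative factor BTG2 at −1.88 ± 0.39. DUSP5 reached an adjusted p of 0.0665 with the batch term. The log2 differences within batches were −2.05 and −2.74 for DUSP1, −2.03 and −1.63 for DUSP5 and −2.34 and −1.64 for BTG2. The noncoding RNA LINC01358 was at 3.76 ± 0.70. MCF2L had 0 counts in both TPA libraries and 2 and 12 counts in the TPA+H89 libraries. NR4A3 was at −1.91 ± 0.50, JUNB at −2.40 ± 0.89, FOS at −0.31 ± 1.04 and EGR1 at 0.19 ± 0.77. Without TPA 2 the JUNB value was 0.0933.

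The immediate-early list was lower in TPA+H89 than in TPA, with a median of −1.18 and 22 of 24 members negative (adjusted p = 1.0e-09, but adjusted p = 0.147 with an estimated correlation). Over all genes 0 members passed, 2 were lower when adjusted over the list alone, and 13 when so adjusted with the batch term. Its median within batches was −0.50 and −1.26. The feedback regulators had a median of −0.85 with 5 lower when adjusted over the list alone (adjusted p = 0.174 with an estimated correlation), and the cAMP and CREB targets one of −0.44 with 2 lower (adjusted p = 0.0529 with an estimated correlation). Medians of −1.10, −1.05 and −0.87 were found for the genes studied earlier for MSK, the NF-kappaB targets and the secreted factors (adjusted p = 0.147, 0.352 and 0.352 with an estimated correlation). The SRF and MRTF targets (−0.32) and the p53 targets (−0.23) also lost their calls (adjusted p = 0.600 and 0.359 with an estimated correlation, and 0.0506 and 0.0779 with the batch term at the preset correlation). The 6 small structured RNAs left after rRNA depletion had a median of 2.15 (adjusted p = 0.000129, but adjusted p = 0.239 with an estimated correlation), and TPA+H89 1 was the library richest in RMRP. Without TPA 1, 171 genes were higher and 548 lower.

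EGF was next compared with control in the presence of the inhibitor. EGR2 rose by 5.20 ± 0.56 in EGF+H89 against H89 (adjusted p = 0.00855), from 6.58 ± 1.65 to 241 ± 1.86 CPM (n = 3 and 2). The membrane protein gene TMEM88 rose by 4.99 ± 0.70, from a level of 0.0572 ± 0.0373 CPM, KLF10 by 3.28 ± 0.45, CSRNP1 by 2.85 ± 0.39 and the homeobox factor TGIF1 by 1.86 ± 0.26. These were 5 higher and 0 lower, with 284 genes at an unadjusted p under 0.05, and the batch term gave 50 higher and 0 lower. In that fit LIF, IER3, FOSB, JUNB, ATF3 and DUSP1 rose by 3.59, 3.83, 4.56, 3.44, 2.42 and 2.36. Of the immediate-early factors 2 rose, 15 when adjusted over the list alone and 9 with the batch term (median 2.24; adjusted p = 0.000708 with an estimated correlation). The feedback regulators (median 0.52) and cAMP and CREB targets (0.23) had adjusted p = 0.0320 and 0.00728 with an estimated correlation, but lost their calls with the batch term and an estimated correlation (adjusted p = 0.160 and 0.0777). The secreted factors (0.72), NF-kappaB targets (0.63), p53 targets (0.24) and small structured RNAs (0.65) were higher, and the cholesterol synthesis (−0.65), SRF and MRTF (−0.52) and S phase genes (−0.24) lower, at the preset correlation alone (adjusted p = 0.102, 0.319, 0.192, 0.352, 0.498, 0.370 and 0.233 with an estimated correlation). The small structured RNAs were not called with the batch term at the preset correlation (adjusted p = 0.0520). Without H89 3 the cholesterol and fatty acid synthesis list reversed and was not called (adjusted p = 0.0940). DESeq2 called 54 higher and 1 lower, and leaving out any 1 of the 3 H89 libraries left 0 calls.

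The same comparison was made with TPA. HES1 rose by 7.56 ± 1.16 in TPA+H89 against H89 (adjusted p = 0.0314), from 0.506 ± 0.454 to 100.0 ± 48.6 CPM (n = 3 and 2). DUSP2 rose by 5.88 ± 0.80, EGR2 by 5.58 ± 0.57, NR4A1 by 5.49 ± 0.77, TMEM88 by 5.33 ± 0.71 and BHLHE40, a clock-related repressor, by 4.19 ± 0.62. KLF10, LIF, ATF3, NR4A3, DUSP5 and SPRY2 rose by 3.56, 3.26, 3.15, 2.71, 1.93 and 1.69. In all 18 genes were higher and 0 lower, with 723 at an unadjusted p under 0.05, and the batch term gave 80 higher and 0 lower, with FOSB rising by 7.41 and EGR1 by 3.65. Of the immediate-early factors 7 rose, 18 when adjusted over the list alone and 14 with the batch term (median 2.93; adjusted p = 0.000708 with an estimated correlation). The cAMP and CREB targets kept their call with an estimated correlation (adjusted p = 0.00337) but not with the batch term as well (adjusted p = 0.0807), and the feedback regulators, with 3 of 18 members higher, did not (adjusted p = 0.102 with an estimated correlation). The small structured RNAs (median 1.67), histone genes (0.65), cholesterol synthesis genes (0.50), secreted factors (0.25) and stress response genes (0.09) were higher at the preset correlation alone (adjusted p = 0.147, 0.290, 0.413, 0.352 and 0.609 with an estimated correlation). Without TPA+H89 1 the histone and stress response lists reversed and were not called (adjusted p = 0.789 and 0.616), and the stress response list was not called with the batch term at the preset correlation (adjusted p = 0.0779). DESeq2 called 83 higher and 1 lower, and leaving out H89 1, 2 or 3 left 1, 0 and 0 calls.

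**Figure D3:**
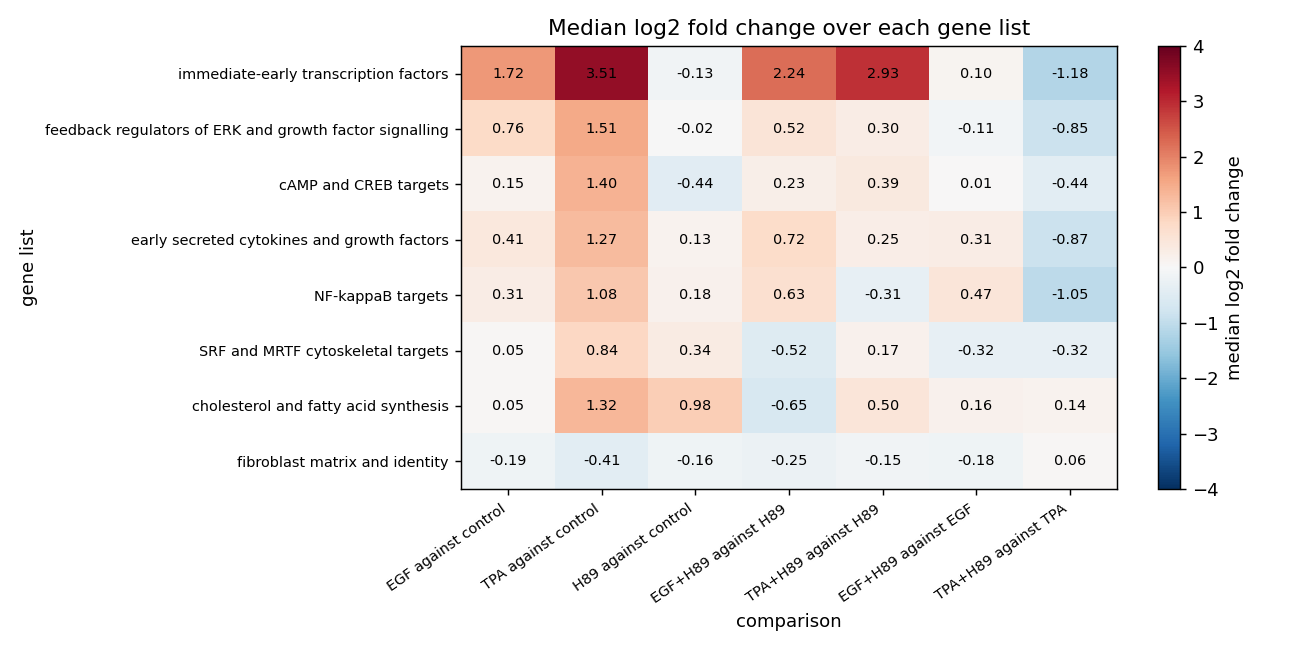
Median log2 fold change over the tested members of 8 gene lists in 7 comparisons, on a colour scale from −4 to 4. The immediate-early factors stood at 1.72 and 3.51 with EGF and TPA, at 2.24 and 2.93 with H89 present, and at 0.10 and −1.18 when the inhibitor was compared within a mitogen.

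Whether the responses differed with the inhibitor was tested as an interaction. For EGF by H89, 0 genes passed by edgeR, with 48 at an unadjusted p under 0.05, and 0 with the batch term and by DESeq2. The lowest p-values were those of ZNF93 (−1.96 ± 0.54), TMEM88 (2.94 ± 0.88), CDHR5 (−2.88 ± 0.86), PCF11 (−0.92 ± 0.29) and EP300-AS1, which lay near the detection limit in all groups. For TPA by H89, 0 genes passed by edgeR, with the batch term and by DESeq2, with 887 at an unadjusted p under 0.05 by edgeR, and 126 passed without TPA 1. LINC01358 had the lowest p (4.38 ± 0.85; adjusted p = 0.900), followed by TLE6, MCF2L and CHN2, which had 0 counts in both TPA libraries, and ARHGEF16, which had 0 and 3 counts in the TPA+H89 libraries. DUSP1 was at −2.43 ± 0.67. The immediate-early list had a median of 0.28 in the EGF interaction (adjusted p = 0.167) and −0.79 in the TPA interaction (adjusted p = 9.2e-06, but adjusted p = 0.263 with an estimated correlation).

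The genes induced by each mitogen, those called higher by at least 1 on the log2 scale, were then followed under H89. The 5 EGF-induced genes had a median log2 fold change of 2.81 for EGF and 2.35 for EGF against control with H89 present. Their median for EGF+H89 against EGF was −0.61; over all genes 0 were lower, and 2, DUSP5 (−1.16 ± 0.33) and ERRFI1 (−0.75 ± 0.26), were lower when adjusted over the list alone. A limma fit of log2 CPM, used for shuffled residuals, chose 7 genes with a median of −0.52. Of 100 shuffles, 17 gave a median as low. The residuals were taken from means pooled over H89. They thus still held any inhibitor effect, and the shuffles could not decide on selection for either mitogen. The 72 TPA-induced genes had medians of 3.26 and 1.91 and a median of −0.85 for TPA+H89 against TPA, with 68 negative and 4 positive. Of these, 0 were lower over all genes and 6 when adjusted over the list alone, including DUSP1, DUSP5, NR4A3 and MAFF. The limma fit chose 54 genes with a median of −0.78, and 10 of 100 shuffles gave a median as low. Without control 1, EGF 1 and TPA 2 the edgeR fit gave 46 TPA-induced genes with a median of −0.39, 36 of them negative. It gave 23 EGF-induced genes with a median of −0.026, 13 negative and 10 positive. Without EGF 1 alone the EGF-induced median was −0.14. Both lists were chosen on these samples, so the counts adjusted over them are not independent evidence. With the batch term the lists had 41 and 176 genes, medians of −0.19 and −0.88, and 2 and 65 genes lower when adjusted over the list alone. With limma quality weights, 93 EGF-induced genes had a median of −0.19, with 63 negative and 30 positive. Of these, 7 were lower over all genes and 28 when adjusted over the list alone. For 19 TPA-induced genes the median was −0.93 and these counts were 0 and 3.

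TPA was also compared with EGF directly. By edgeR 0 genes passed, with 2480 at an unadjusted p under 0.05; the batch term gave 38 higher and 24 lower, and DESeq2 called 170 higher and 130 lower. With the batch term NR4A3 was higher with TPA by 2.72 ± 0.33 (adjusted p = 0.00277), DUSP2 by 4.10 ± 0.51, NR4A2 by 3.10 ± 0.53, INSIG1 by 2.75 ± 0.48, IER3 by 2.60 ± 0.46 and SPRY2 by 1.63 ± 0.25, and EGFL6 was lower (−5.08 ± 0.80). MCF2L, with 0 counts in both TPA libraries, stood at 0.578 ± 0.076 CPM with EGF. The immediate-early list was higher with TPA, with a median of 1.51, 0 members called over all genes, 15 adjusted over the list alone and 7 with the batch term (adjusted p = 2.7e-18, and adjusted p = 0.0427 with an estimated correlation). The MSK list (1.78) and the cAMP and CREB targets (0.58) were also higher (adjusted p = 0.0427 and 0.0168 with an estimated correlation). All 3 lists lost their calls when the batch term was added to the estimated correlation (adjusted p = 0.160, 0.147 and 0.101). Without TPA 1, 1165 genes passed.

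The EGF and TPA responses were set against each other in a fit of the control, EGF and TPA libraries. Across 18131 genes, which are not independent replicates, Pearson's r of the log2 fold changes was −0.0485 and the covariance −0.0419. The sign of r depended on the fit, with 0.130 for no filter, 0.132 for the stricter filter and 0.148 for the block of name sets. Leaving out 1 library moved r more, from −0.291 without EGF 3 to 0.659 without EGF 1. Unchanged groups simulated against the same controls gave an r of 0.460 and a covariance of 0.676 (means of 10 simulations). These were drawn with no batch, while control 1 and EGF 1 share a batch that holds no TPA library. They are therefore no fair reference for the fit without the batch term. With the batch term r was 0.205 and the covariance 0.118, beside 0.451 and 0.198 in simulations. In that fit 21 genes were higher with EGF and 132 with TPA, and 21 were in both sets, against 0.153 for independent lists; part of that excess may come from the shared controls, which were too few to split.

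Most markers of other cell types were low in these cultures. The median level over the markers was at most 0.518 CPM for keratinocytes, 0.434 for endothelial cells, 0.976 for melanocytes and 0.494 for leukocytes, each in EGF 1. Single genes were higher, with maxima of 38.6 CPM for DSP, 44.4 for KRT10, 51.8 for MITF and 76.2 for CD68, and EGFL7 stood at 53.3 in TPA 2 against 6.38 to 15.6 in the other libraries. In EGF against control the median log2 fold changes were 0.25, −0.14, 0.14 and 0.35, and in TPA against control 0.02, −0.41, −0.32 and −0.79, and none of these lists passed in either comparison. The keratinocyte list with TPA had a mean of −0.59 and a test direction of higher, and the leukocyte list with EGF a mean of 0.0066 and a test direction of lower. The melanocyte list was lower in H89 against control (median −0.70; adjusted p = 0.0252, but adjusted p = 0.243 with an estimated correlation) and in EGF+H89 against EGF (−2.79; adjusted p = 0.00117, but adjusted p = 0.102 with an estimated correlation), and its median was −0.21 and −0.50 with the batch term.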

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

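The interaction tests, leaving out 1 library, and the tests of library depth and of selection on EGF-induced genes were set before their results were seen, and the other tests in this part were chosen only after the result was seen. At the preset correlation of camera, interaction tests called 16 gene lists, and with an estimated correlation 0 of these were called, the lowest adjusted p being 0.137 for the melanocyte markers in TPA by H89. For EGF by H89 the called lists were SRF and MRTF targets (median −0.62), NF-kappaB targets (0.22), S phase and mitosis genes (−0.36), FOXO and growth-arrest genes (0.23) and cholesterol synthesis genes (−0.86). For TPA by H89 they were the immediate-early factors (−0.79), feedback regulators (−0.78), secreted factors (−1.02), SRF and MRTF targets (−0.63), cAMP and CREB targets (−0.25) and NF-kappaB targets (−1.33). The others were cholesterol synthesis genes (−0.91), p53 targets (−0.17), genes studied earlier for MSK (−1.12), melanocyte markers (0.85) and small structured RNAs (2.40). The p53 targets were not called with the batch term at the preset correlation (adjusted p = 0.225). No single gene passed either interaction in the main fit or with the batch term on all libraries. In EGF by H89 the cholesterol synthesis list reversed and lost its call without H89 3 (adjusted p = 0.953), and the NF-kappaB list did so without EGF 1 and without control 3 (adjusted p = 0.705 and 0.601).

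The TPA-induced genes were lower with H89, which the inhibitor or TPA 2 alone could explain. In the pair TPA+H89 1 and TPA 1, without TPA 2, their median difference was −0.60 with 58 of 72 lower, beyond the bound of −0.2. The spread of 0.444, the interquartile range over the genes divided by 2, shows how genes differ and not the error of the median. This pair holds 1 library per group, and TPA 1 helped to choose the genes, so TPA 2 alone stayed open. The pair with TPA 2 gave −1.06 with 66 of 72 lower. Fits without TPA 2 gave −0.71 over 13 genes, 13 of them lower, and, without control 1 and EGF 1 as well, −0.39 over 46 genes, 36 of them lower. Selection of genes high in the TPA libraries was not excluded. Of 100 shuffles, 10 gave a median as low as the −0.78 of 54 genes chosen in the limma fit used for them. That fit had no batch term, and the shuffles moved residuals across batches. The residuals were taken from means pooled over H89, so they still held any inhibitor effect, and the shuffles could not decide on selection. For the 41 genes chosen by EGF with the batch term, the median for TPA+H89 against TPA was −0.65, with 35 of 41 lower. This lay beyond the bound of −0.2 by more than the median SE of 0.377, so selection became less likely for them. Selection was not excluded, because that SE does not measure the error of a median over genes that respond together. Of these 41 genes, 35 were also called higher with TPA against control.

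TPA 2 stood apart from the other libraries, with a median correlation of 0.936. After the trend with GC content was removed this became 0.946, above the lowest other library with paired counts, TPA+H89 1 at 0.943, so GC bias could account for part of it. As TPA+H89 1 had the fewest counts of all libraries, passing it says little. The SD of the log2 difference between TPA 2 and TPA 1 went from 1.28 to 1.09. Thinned in 5 draws to the median total of the other libraries, TPA 2 reached at most 0.93565, against 0.94335 for the lowest other. Thinning adds sampling noise and was unlikely to raise the correlation, so this test could not decide on depth. Because TPA 2 is in a design group, a biological cause was possible but was not tested.

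Part of the immediate-early list was high in control 1, which shares a technical batch with EGF 1. The excess of control 1 over the other controls had a median of 0.55, with 7 of 24 members below them, and was largest for FOSB (5.98), FOS (3.93) and EGR4 (2.60). The excess of control 1 less that of EGF 1 had a median of 1.11 with a spread over the genes of 1.23 (the interquartile range divided by 2). That spread does not measure the error of the median, and the batch stayed possible. For the number of genes called, each comparison of 3 with 3 libraries had 10 splits, too few for a share under 0.05. EGF against control gave 5 genes, and 3 of 10 splits gave as many. The highest other was 148, for control 1, EGF 1 and EGF 2 against the rest. With control 2 in place of EGF 2 that split gave 140, but with control 3 or EGF 3 it gave 0. With the batch term the real split gave 41 and the highest other 2, so 1 of 10 gave as many. For H89 against control all 10 gave as many, with 0 for the real split and 0 for the highest other.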

How the results depend on the processing

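The tests with the GC correction, both control copies, or without control 1, EGF 1 and TPA 2 were chosen after seeing the data. Of the named genes with a result, 109 of 111 kept their direction and side of the threshold with size factors, 105 of 108 with the stricter filter, 105 of 111 with no filter and 79 of 107 by DESeq2, and the other 28 gained a call there. In the main edgeR fit an added log2 fold threshold of 1 changed no count of calls. With the technical batch term 83 of 111 did so and 27 gained a call. Leaving out 1 library kept 465 of 629 values for genes and 448 of 547 for lists. The cause was not tested where none is given. The effect of depth on TPA+H89 1, with 7527026 counts, was not tested.

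The technical batch term gave 41 genes for EGF against control, 233 for TPA against control, 50 for EGF+H89 against H89, 80 for TPA+H89 against H89 and 62 for TPA against EGF. In simulations its calls held more false ones than the 5% aimed at. A block for sets of sample names gave 22, 44, 76 and 10 for EGF against control, EGF+H89 against H89, TPA+H89 against H89 and TPA against EGF, and 1 for TPA+H89 against TPA. For TPA against control it gave 83, of which 50 were among the 77 called without it. Pairs of libraries of different groups in the same name set had a median residual correlation of 0.274, and those in the same technical batch 0.293. With only the compared groups in the fit, EGF and TPA against control gave 0 each and EGF+H89 against H89 gave 49.

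Quality weights gave 114 for EGF and 19 for TPA against control, 21 for EGF+H89 against EGF, 213 and 69 for EGF+H89 and TPA+H89 against H89, 1 for TPA against EGF and an r of 0.344 between EGF and TPA. DESeq2 gave 62, 524 and 3 for EGF, TPA and H89 against control, 1 and 9 for EGF+H89 against EGF and TPA+H89 against TPA, 55 and 84 for EGF+H89 and TPA+H89 against H89 and 300 for TPA against EGF. With no filter EGF+H89 against H89 gave 9. Both control copies gave 11 for EGF and 157 for TPA. The GC correction gave 10 for EGF against control and 35 for TPA+H89 against H89; with the batch term it gave 58 and 276 for EGF and TPA, 57 and 96 for EGF+H89 and TPA+H89 against H89, and 53 for TPA against EGF.

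Without control 1, EGF 1 and TPA 2 there were 23 and 46 for EGF and TPA against control, 45 and 79 for EGF+H89 and TPA+H89 against H89, medians of −0.026 and −0.39 for EGF-induced and TPA-induced genes under H89 and an r of 0.343. The batch term without these gave 49 for EGF, 1 for TPA+H89 against TPA, 71 and 102 for the comparisons with H89, 1 for TPA by H89, 1 for TPA against EGF and −0.0419 and −0.60 for EGF-induced and TPA-induced genes. Of 91 list calls, 18 held with an estimated correlation and 8 with that and the batch term. Testing lists against no change, which is another question, 14 of the 200 tests passed by directional fry and 35 by mixed fry, which gives no direction.

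FOSB with EGF reversed to 1.11 with the batch term, 1.14 with name sets, 3.34 with weights, 2.36 without the 3 libraries, 2.53 without them with the batch term and 1.03 with the GC and batch terms. In TPA+H89 against TPA, JUNB reversed to 0.0892 without the 3 libraries, FOS to 0.0335 without them with the batch term and EGR1 to −0.0152 with name sets. The NF-kappaB list in H89 against control reversed, at an adjusted p of 0.725 with the batch term, 0.928 with that and an estimated correlation, 0.752 with name sets and 0.872 without the 3 libraries; in TPA against EGF it reversed at 0.595 without them.

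Leaving out each library in turn, with a lone sample assumed to vary like the other groups, gave 0 to 10 genes for EGF and 13 to 1187 for TPA against control, 0 to 719 for TPA+H89 against TPA, 0 to 1 for EGF+H89 against H89, 0 to 17 for TPA+H89 against H89, 0 to 126 for TPA by H89 and 0 to 1165 for TPA against EGF. The median of induced genes under H89 ran from −1.16 to −0.14 for EGF and from −1.73 to −0.63 for TPA. For EGF the −1.16 rests on 1 gene, and no gene was induced without control 2, EGF 2, EGF+H89 1 or EGF+H89 2. The value of r ran from −0.291 to 0.659. FOSB with EGF ran from −1.20 to 2.63, and in TPA+H89 against TPA JUNB from −3.42 to 0.0933 and EGR1 from −0.28 to 0.58. The adjusted p of lists ran from 2.59e-07 to 0.779 for NF-kappaB targets with EGF (reversed without control 1 or EGF 2), 4.28e-06 to 0.945 with H89 and 1.27e-05 to 0.705 in EGF by H89. It ran from 1.07e-08 to 0.0940 for cholesterol and fatty acid synthesis in EGF+H89 against H89 and 2.36e-12 to 0.953 in EGF by H89, and in TPA+H89 against H89 from 1.16e-05 to 0.616 for the unfolded protein and integrated stress response and 9.09e-08 to 0.789 for histone genes. A change of pseudocount was not run because the values are counts, and the 2 and 2 split of controls was not run because 3 were distinct.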
